A study of Arabidopsis thaliana with 18 samples.

How the data were processed

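Total RNA from whole Col-0 seedlings was profiled on Affymetrix ATH1 arrays, 18 in all, with 3 biological replicates in each of 6 groups (wild type, LBD37 overexpresser and LBD38 overexpresser without added nitrogen, and wild type, lbd37 and lbd38 mutants with 4 mM KNO3). The labels state both liquid culture throughout and growth on agar before a transfer to liquid wells, and the conflict was left open. RNA was prepared with a commercial kit and labelled with biotin. The values used are the deposited log2 signals, 1 per probe set and array, which the authors made from the array images by RMA per the submitters' processing notes. The RMA version is not given in the sources used here. The image files were not used here, so background correction and probe summary could not be varied.

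All 18 value columns were matched to samples by their identifiers. The table holds 22810 probe sets, of which 64 are controls. The controls were left out of the tests, leaving 22746. Their values, among them the probe set for 25S ribosomal RNA, were compared between groups by exact permutation tests. Array medians and interquartile ranges, correlations within groups and the ratio of 3' to 5' actin signal were computed for every array. In 28 such permutation tests of array quality the smallest p was 0.1, the lowest that 3 against 3 arrays can give.

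Gene names came from the platform's table of probe sets, matched to gene symbols of the TAIR10.1 assembly. The table lists exactly 1 gene for 13513 probe sets (13355 distinct genes), several for 503 and none for 8730. Of the probe sets with 1 gene, 13436 matched a current locus and 1580 of these had a symbol. Probe sets with several genes or none are given by identifier only. No probe set was listed with LBD37, LBD38 or LBD39.

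Fold changes were estimated with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes without a trend) on all 18 arrays with 6 group means, giving 12 residual degrees of freedom and a prior of 5.89. There were 7 comparisons: nitrogen-depleted against replete wild type, each overexpresser against depleted wild type, the overexpressers against each other, each mutant against replete wild type, and the mutants against each other. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method within each comparison over 22746 probe sets, with a threshold of 0.05. Standard errors are those of limma, which pool the spread of all groups. The p-values measure only the spread between these samples. A probe set was said not to overlap when every array of one group lay above every array of the other, which 10% of unchanged probe sets would do by chance.

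Genes were named by a rule written before the values were seen. For nitrogen depletion, each overexpresser and each mutant it takes the 8 rising and 8 falling probe sets with the largest change among those past the threshold, with no overlap between arrays and exactly 1 listed gene. For the 2 comparisons between lines it takes 5 of each, and fewer where fewer pass. Up to 4 members per gene list with the largest change may be added, and a gene named in one comparison may be followed in others.

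Gene lists were tested with camera from limma, with an inter-gene correlation of 0.01, and again with a correlation estimated from the residuals. There were 22 lists fixed before the values arrived and 17 added after the probe annotation was read and before any comparison was run. Lists with at least 3 measured members, 27 in all, were tested, and p-values were adjusted over these 27 within each comparison. Each gene entered once. Members past the threshold were counted after adjustment over all probe sets and after adjustment over the list alone. Of 189 list tests 60 passed, and 3 of these passed with the estimated correlation: senescence and autophagy and autophagy genes under nitrogen depletion, and rapid defence and calcium signalling genes in lbd37. In 30 list tests the median, the mean and the test differed in sign, and the lowest adjusted p among them was 0.194. Every list past the threshold kept the sign of its median under the other scalings.

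Fold changes of pairs of comparisons were related by correlation, covariance and counts of shared calls. Where 2 comparisons share control arrays, 100 simulated data sets with unchanged groups and the same shared controls gave the covariance that sharing alone produces. Their correlations lack the spread that real changes add and are not comparable with the observed ones. Counts expected for independent lists are products of the list sizes over the number of probe sets.

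Alternatives written before the data were examined were a replicate block, repeated quantile normalization, centring of each array, leaving out the dimmest 40% of probe sets, fitting only the groups compared, eBayes with a trend and robust, array weights, only probe sets with 1 gene, a 2-fold minimum, an adjusted p under 0.01, and leaving out each array. For lists they were the estimated correlation, the replicate block, fry, all probe sets of a gene and the filter on dim probe sets. Other splits of the 6 arrays of each comparison were also fitted.

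The tests were tested on simulated data with 200 of 22746 probe sets changed. Of 67 changed 1.5-fold, 76.1% to 94.0% were recovered depending on the comparison, of those changed 2-fold 98.5% to 100%, and of those changed 4-fold 100%. There were 4 to 17 false calls among the 190 to 211 calls of a comparison. The simulated noise was independent between probe sets and arrays, so the effect of an array that stands apart was not covered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.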

Results

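Transcripts were measured in whole Arabidopsis thaliana seedlings of the Col-0 accession on 18 Affymetrix ATH1 arrays, with 3 biological replicates in each of 6 groups. All seedlings were 9 days old. In the nitrogen-depleted groups, wild type and overexpressers of LBD37 and of LBD38 spent 7 days with 4 mM KNO3 and then 2 days in medium to which no nitrogen was added. In the nitrogen-replete groups, wild type and T-DNA insertion mutants of LBD37 and of LBD38 had 4 mM KNO3 for 9 days. LBD37 and LBD38 are transcription factors of the LATERAL ORGAN BOUNDARY DOMAIN family, and the design asks which transcripts respond to nitrogen supply and to gain or loss of each factor.

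The array medians lay between 6.87 and 7.06 on the log2 scale. Replicates within a group correlated across probe sets at r of 0.988 to 0.998. The LBD37 overexpresser's replicate 3 stood apart, with the lowest median (6.87) and an interquartile range of 2.89 against 3.06 to 3.28 on the other 17 arrays. The labels call the replicates biological without saying what was repeated, so p-values refer to the spread between these samples, and 3 arrays per group limit the precision. The transcripts of LBD37, LBD38 and LBD39 could not be picked out among the probe sets tested, because the annotation used pairs none with them by name. The targeted genes therefore could not serve as a check of the labels.

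**Figure D1:**
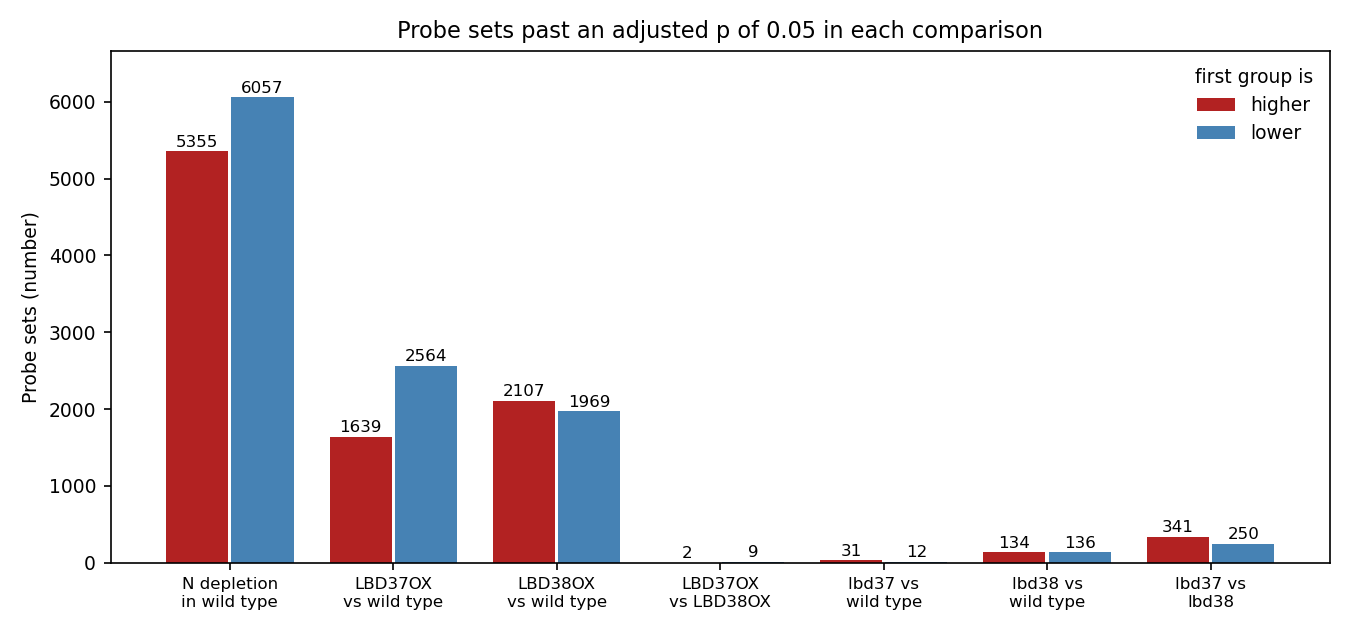
Number of probe sets past a limma adjusted p of 0.05 in each of the 7 comparisons, with bars from 0 for probe sets higher and lower in the group named first. Nitrogen depletion changed 11412 probe sets and the overexpressers 4203 and 4076, whereas the lbd37 and lbd38 mutants differed from wild type at 43 and 270.

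Nitrogen depletion in wild type was examined first, as the background on which the overexpressers were profiled. NRT2.5 (AT1G12940), a high-affinity nitrate transporter, rose 14.9-fold, from 6.11 ± 0.11 to 10 ± 0.09 (log2 signal, mean ± SD, n = 3; limma adjusted p = 7.36e-11). The largest rises among probe sets with 1 listed gene were those of AT5G39520 (49.1-fold, 5.34 ± 0.22 to 10.96 ± 0.09, adjusted p = 1.95e-10), AT1G80130 (35.3-fold), AT3G28510 (34.2-fold) and AT4G32950 (16.8-fold). AT1G76960, AT1G64360 and AT3G13950 rose 15.8-, 14- and 14-fold. Among the same probe sets the largest falls were those of AT1G47400, a peptide of the IRON MAN family that acts in iron deficiency (19.6-fold lower, 9.11 ± 0.30 to 4.82 ± 0.04, adjusted p = 1.28e-10), AT1G49500 (19.4-fold), AT2G19970 (18.6-fold) and AT1G73120 (15.5-fold). AT3G15450, the jacalin-type lectin gene JAL33 (AT3G16450), the methionine sulfoxide reductase gene MSRB6 (AT4G04840) and AT5G18600, a CC-type glutaredoxin, were 11-, 10.8-, 9.00- and 8.99-fold lower.

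All 5 measured genes of anthocyanin synthesis, of 11 listed, rose with nitrogen depletion, as did all 5 when adjusted over the list alone. Dihydroflavonol reductase (DFR, AT5G42800) went from 9.97 ± 0.38 to 12.17 ± 0.08 (4.60-fold, adjusted p = 2.02e-07). The glycosyltransferase genes AT4G14090 and UF3GT (AT5G54060) rose 4.56- and 4.50-fold, and the acyltransferase gene AT5MAT (AT3G29590) 2.88-fold. The list had a median log2 change of 2.17 (camera, adjusted p = 4.96e-05), and an adjusted p = 0.216 with an estimated correlation. All 16 measured genes for senescence and autophagy, of 30 listed, rose too (16 adjusted over the list alone; median 1.1, adjusted p = 3.97e-12), and this call held with an adjusted p = 0.00941 with an estimated correlation. Among them were the ubiquitin-like autophagy genes ATG8B (AT4G04620, 4.38-fold) and APG8A (AT4G21980, 3.62-fold) and pyruvate orthophosphate dikinase (PPDK, AT4G15530, 3.13-fold).

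Of 9 measured genes for cytosolic ribosomal proteins, 7 fell (7 adjusted over the list alone), with a median of −0.23 (camera, adjusted p = 0.0411; adjusted p = 0.527 with an estimated correlation). The falls of AT5G02870 and AT2G01250 were −0.42 ± 0.09 and −0.41 ± 0.07 on the log2 scale (estimate ± SE). The 3 measured genes of the fixed photosynthesis list, of 23 listed, were LHCB4.1 (AT5G01530), LHCB4.2 (AT3G08940) and RCA (AT2G39730). They changed by −0.85, −0.97 and −0.35, each past the threshold (3 adjusted over the list alone), while the list test on these 3 gave an adjusted p = 0.0766. The Aurora kinases AUR1 (AT4G32830) and AUR2 (AT2G25880), which act in cell division, fell by 1.02 and 1.51.

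Several lists kept fewer than 3 measured members and had no list test. In these, APL3 (AT4G39210), a large subunit of ADP-glucose pyrophosphorylase in starch synthesis, rose 8.42-fold (6.0 ± 0.21 to 9.07 ± 0.06, limma adjusted p = 8.49e-09) and APL4 (AT2G21590) changed by 0.55. The glutaredoxin gene GRX480 (AT1G28480) rose 3.54-fold, AT5G41670 2.13-fold, AT3G25790 1.83-fold and HCT (AT5G48930) 1.59-fold. The nitrate transporter gene AT2G26690 was 2.01-fold lower and the response regulator ARR15 (AT1G74890) changed by −0.64.

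Markers of root and shoot tissue moved both ways. Among 4 measured root markers, EXPA7 (AT1G12560), EXPA18 (AT1G62980) and AT4G26010 rose by 0.51, 0.74 and 0.94, and PYK10 (AT3G09260) fell by 1.27 (list adjusted p = 0.491; 3 rose and 1 fell adjusted over the list alone). Among 3 measured leaf markers, the stomatal regulator SPCH (AT5G53210) and YAB3 (AT4G00180) fell by 1.41 and 0.81 and FMA (AT3G24140) rose by 0.24 (list adjusted p = 0.37; 1 rose and 2 fell adjusted over the list alone). Lists for glucosinolate synthesis (1 of 3 fell, AT2G31790; 1 adjusted over the list alone; adjusted p = 0.37), jasmonate (median 0.13, adjusted p = 0.74), early flavonoid synthesis (1 of 3 rose, CHIL; 1 adjusted over the list alone; adjusted p = 0.74) and reference genes (median 0.03, adjusted p = 0.74) did not pass.

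In all, 11412 of 22746 probe sets differed between nitrogen-depleted and replete wild type, 5355 higher and 6057 lower (limma, adjusted p threshold 0.05), of which 1165 and 1125 changed at least 2-fold. The arrays of the groups did not overlap at 58.3% of probe sets, against 10% by chance. The median log2 change over all probe sets was −0.07. Among unnamed probe sets, 264400_at was 45.2-fold higher, and 254550_at and 267262_at were 103- and 28.6-fold lower. Depleted wild type read 4.47 and 4.38 at the latter, below the lower quartile of every array (5.19 to 5.34), so these folds are rough. The same holds for AT1G47400 (4.82 in depleted wild type) and AT3G28510 (4.57 in replete wild type). In later comparisons it holds for AT4G27654 and AT1G59265 (4.65 and 4.43 in depleted wild type). It also holds for AT5G02580 (5.12 in the LBD37 overexpresser) and PDF1.2 (4.41 in replete wild type and 4.37 in lbd37), among others.

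**Figure D2:**
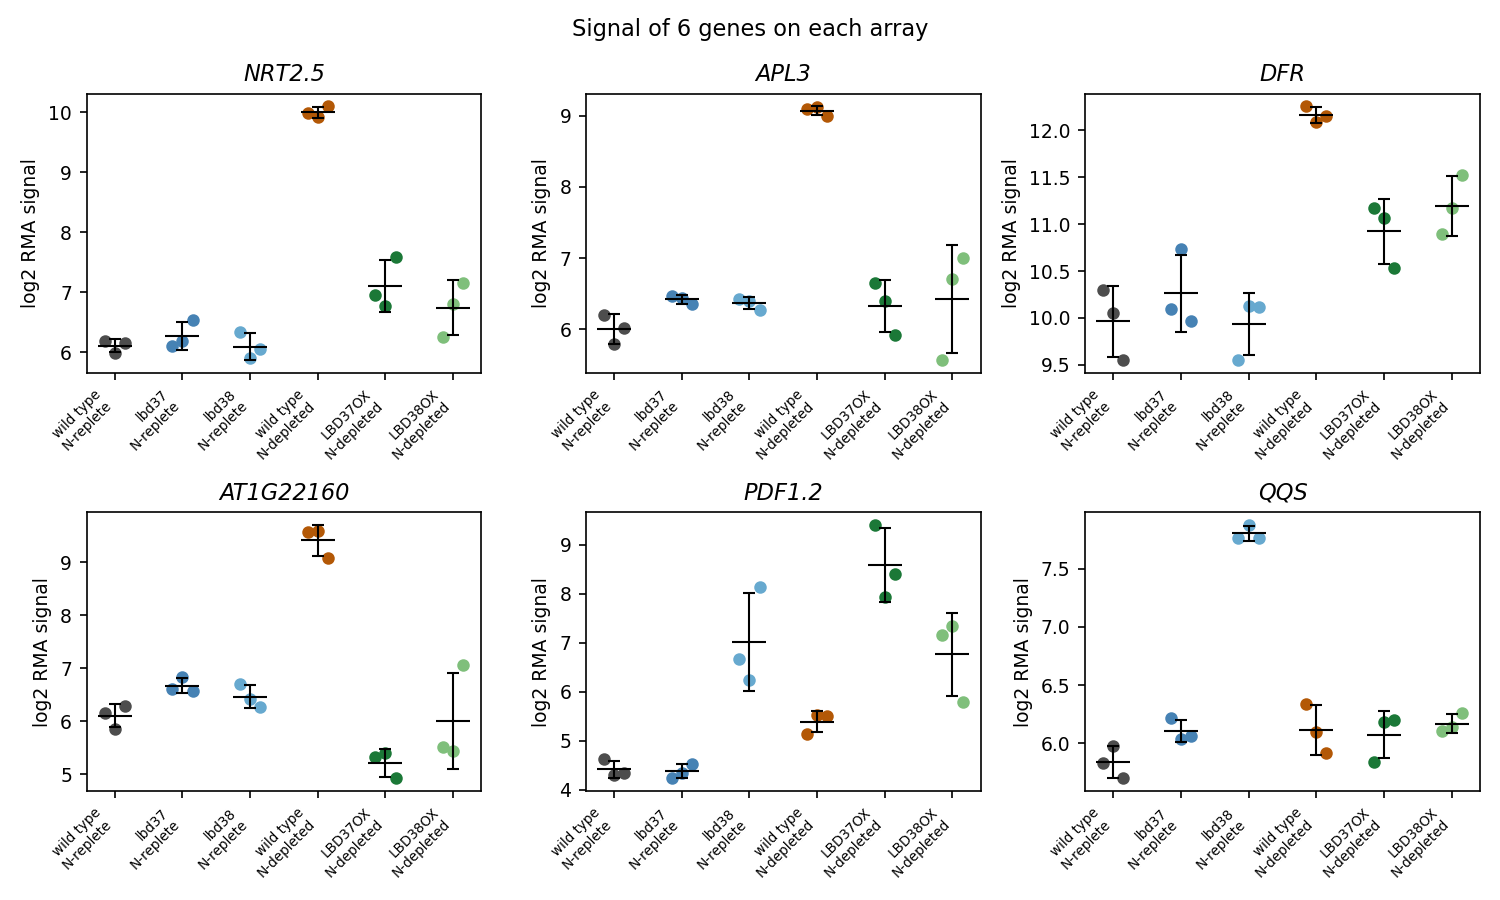
Log2 RMA signal of NRT2.5, APL3, DFR, AT1G22160, PDF1.2 and QQS on each of the 18 arrays (points), with the mean ± SD (n = 3) of each of the 6 groups. NRT2.5 averaged 10 in nitrogen-depleted wild type against 7.10 and 6.74 in the LBD37 and LBD38 overexpressers, and QQS 7.80 in the lbd38 mutant against 5.84 in replete wild type.

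Overexpression of LBD37 was compared with wild type under nitrogen depletion. AT1G22160 was 18.3-fold lower in the overexpresser (5.22 ± 0.26 against 9.41 ± 0.29, n = 3, limma adjusted p = 3.53e-08), followed by AT5G02580 (11.9-fold), AT5G02230 (10.4-fold) and AT5G38910 (9.16-fold). The CC-type glutaredoxins AT2G47880 and AT3G62960 were 8.46- and 7.94-fold lower, and the nitrate transporter NRT2.5 7.47-fold (7.10 ± 0.43 against 10 ± 0.09, adjusted p = 4.11e-08). AT1G64360 was 7.15-fold lower. The plant defensin PDF1.2 (AT5G44420), a marker of jasmonate and ethylene signalling, was 9.17-fold higher (8.58 ± 0.75 against 5.39 ± 0.22, adjusted p = 3.87e-05). AT4G27654, AT2G19970 and AT4G27652 were 4.50-, 3.65- and 3.63-fold higher, and PDF1.2b (AT2G26020), AT3G03920, AT4G27657 and the zinc finger gene STZ (AT1G27730) 3.3-, 3.27-, 3.2- and 3.19-fold. The PDF1.2b probe set carries the suffix that marks probes shared between transcripts.

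All 5 measured anthocyanin synthesis genes fell in this overexpresser (5 adjusted over the list alone), with a median of −1.24 (camera, adjusted p = 1.89e-06; adjusted p = 0.191 with an estimated correlation). AT4G14090 was 4.06-fold lower, AT5MAT 2.63-fold and DFR 2.37-fold (10.92 ± 0.35 against 12.17 ± 0.08, adjusted p = 0.000843). Of the 16 senescence and autophagy genes 8 fell, or 10 adjusted over the list alone, among them ATG8E (AT2G45170, 2.54-fold lower) and PPDK (1.87-fold). Their median was −0.36 (adjusted p = 1.89e-06; adjusted p = 0.13 with an estimated correlation).

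Of the leaf markers, SPCH rose 2.55-fold and FMA by 0.23, and YAB3 was at 0.26; 3 of 3 passed when adjusted over the list alone (list adjusted p = 0.0141, or adjusted p = 0.191 with an estimated correlation). The jasmonate list passed (adjusted p = 0.0293; adjusted p = 0.191 with an estimated correlation) with 1 of 3 genes past the threshold, or 2 adjusted over the list alone, its mean change of 1.2 lying far from its median of 0.28. That gene was PDF1.2, while the jasmonate methyltransferase gene JMT (AT1G19640) was at 0.28 and THI2.1 (AT1G72260) at 0.13. Early flavonoid synthesis had 2 of 3 genes higher, UGT78D1 (AT1G30530) and UGT78D3 (AT5G17030), at 0.46 and 0.39 (3 adjusted over the list alone; list adjusted p = 0.0563). Of the root markers, EXPA7 and EXPA18 fell by 0.62 and 0.48 (2 adjusted over the list alone; list adjusted p = 0.0943), with a list median of −0.37 that was −0.58 without wild-type replicate 3 and −0.17 without wild-type replicate 1. Ribosomal protein genes (median 0.03, adjusted p = 0.729), photosynthesis genes (−0.01, adjusted p = 0.865), glucosinolate genes (0.17, adjusted p = 0.414) and reference genes (−0.08, adjusted p = 0.414) did not pass as lists. Outside the tested lists, APL3 fell by 2.75, AT3G25790 by 1.00, GRX480 by 0.95 and HCT by 0.36, and AUR1 and AUR2 rose by 0.43 and 0.45.

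The comparison gave 4203 probe sets, 1639 higher and 2564 lower (limma), with 61 and 324 changed at least 2-fold, and the arrays of the groups did not overlap at 31.5% of probe sets against 10% by chance. The split depended on scaling, being 2116 higher and 2130 lower after quantile normalization was repeated and 2241 higher and 2195 lower after each array was centred on its median. Without replicate 3 of the overexpresser, the array that stood apart, it was 1973 higher and 1902 lower, and without wild-type replicate 1 or 2 the count was 2742 or 2736. Fitting only the groups compared gave a count of 2067. The control probe set for 25S ribosomal RNA read 10.88 ± 0.42 in this overexpresser and 9.19 ± 0.77 in wild type (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 arrays can give). Among unnamed probe sets, 246996_at was 35.1-fold higher and 260140_at 23.3-fold lower.

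Among the 8 largest falls and 8 largest rises named for each line, LBD38 overexpression shared more falls than rises with LBD37 overexpression. Sharing here means being named in both lines and is no test of a difference, and 1091 probe sets were higher in both. AT1G22160 was 10.6-fold lower than in wild type (6.01 ± 0.91 against 9.41 ± 0.29, n = 3, limma adjusted p = 6.06e-07), AT5G02580 9.78-fold, NRT2.5 9.61-fold (6.74 ± 0.46 against 10 ± 0.09, adjusted p = 2.48e-08) and AT5G02230 7.52-fold. APL3 was 6.27-fold lower (6.43 ± 0.76 against 9.07 ± 0.06, adjusted p = 1.37e-06), and AT1G64360, AT4G33720 and AT2G47880 were 5.39-, 5.12- and 5.09-fold lower. AT2G19970 and MSRB6, both among the transcripts that nitrogen depletion lowered, were 4.45- and 3.62-fold higher. AT1G59265, AT5G14650, AT4G21870, AT3G15310, AT4G27657 and AT4G27652 were 3.38-, 3.34-, 3.24-, 3.23-, 3.11- and 3.05-fold higher, and the AT1G59265 probe set is one that several similar transcripts can share.

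Of the 5 anthocyanin synthesis genes 4 fell (4 adjusted over the list alone), with a median of −1.0 (camera, adjusted p = 3.9e-05; adjusted p = 0.175 with an estimated correlation). AT4G14090 was 3.16-fold lower and DFR 1.96-fold (11.20 ± 0.32 against 12.17 ± 0.08, adjusted p = 0.00526), and UGT78D2 (AT5G17050), which did not pass, was at −0.13. In the same plants all 3 measured genes of the early flavonoid list rose (3 adjusted over the list alone, camera adjusted p = 0.00319, or 0.175 with an estimated correlation). These were UGT78D1 (1.7-fold), CHIL (AT5G05270, 1.33-fold) and UGT78D3 (0.39 on the log2 scale). UGT78D1 and UGT78D3 are glycosyltransferase genes, and no probe set with 1 listed gene was matched to CHS or CHI of the list. Whether the early steps rose therefore stays largely open. Of the senescence and autophagy genes 6 fell (6 adjusted over the list alone), including PPDK (2.02-fold lower) and WRKY53 (AT4G23810, 1.77-fold), with a median of −0.23 (adjusted p = 5.78e-05; adjusted p = 0.129 with an estimated correlation), which was −0.14 without wild-type replicate 1.

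Glucosinolate synthesis had 2 of 3 genes higher, BCAT4 (AT3G19710, 1.58-fold) and AT2G31790 (1.35-fold) (2 adjusted over the list alone; list adjusted p = 0.0236, or adjusted p = 0.27 with an estimated correlation). SPCH rose 2.75-fold, the leaf-marker list passing with 1 of 3 genes (2 adjusted over the list alone; adjusted p = 0.00684, or adjusted p = 0.175 with an estimated correlation). PDF1.2 and JMT rose 2.59- and 1.41-fold (2 adjusted over the list alone; list adjusted p = 0.0963), and LHCB4.1 by 0.34 (1 adjusted over the list alone; photosynthesis list adjusted p = 0.16). The root markers (median −0.21, adjusted p = 0.21), ribosomal protein genes (0.03, adjusted p = 0.755) and reference genes (−0.03, adjusted p = 0.829) did not pass. AUR1 and AUR2 rose by 0.53 and 0.58, and GRX480, AT3G25790 and HCT fell by 1.16, 0.90 and 0.37.

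The comparison gave 4076 probe sets, 2107 higher and 1969 lower (limma), with 90 and 340 changed at least 2-fold and no overlap between arrays at 35.5% of probe sets against 10% by chance. Without the LBD38 overexpresser's replicate 1 the count was 2603. The 25S ribosomal RNA probe set read 9.76 ± 0.38 against 9.19 ± 0.77 in wild type (exact permutation p = 0.4). Among unnamed probe sets, 252220_at was 52.6-fold higher and 266385_at 13.3-fold lower.

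**Figure D3:**
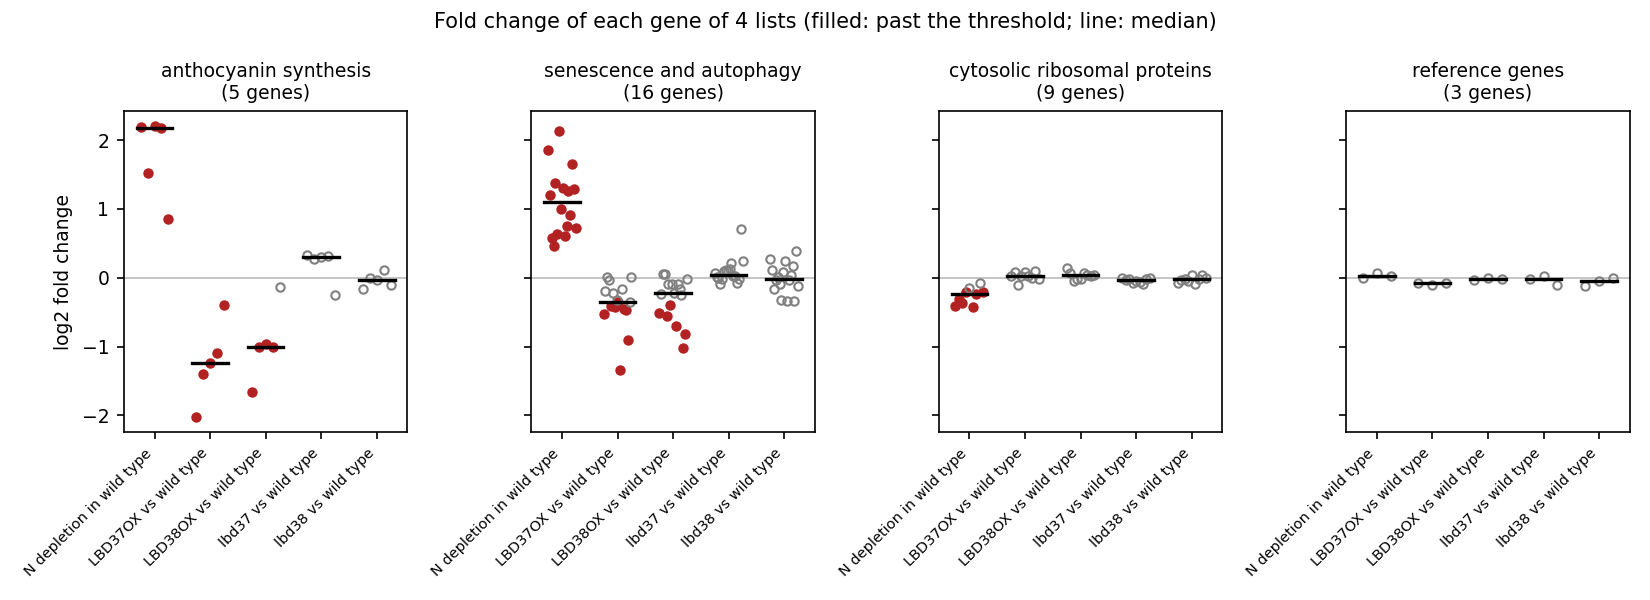
Log2 fold change of every measured gene of 4 lists (5 for anthocyanin synthesis, 16 for senescence and autophagy, 9 for cytosolic ribosomal proteins and 3 reference genes) in 5 comparisons, with filled points past a limma adjusted p of 0.05 and a line at the list median. The anthocyanin median was 2.17 under nitrogen depletion and −1.24 and −1.0 in the LBD37 and LBD38 overexpressers.

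The fold changes of the 2 overexpressers were then set against each other. They correlated across the 22746 probe sets at r = 0.845, where genes are not independent replicates. Unchanged groups simulated with a shared control group of 3 arrays gave a mean of 0.484 over 100 draws (−0.076 to 0.840). These draws lack the spread that real changes add. The covariance was 0.0900 against a simulated 0.00743, a difference of 0.0826. Both lines had 1091 probe sets higher and 1624 lower, where independent lists of these sizes would share 151.8 and 222.0, and 2 probe sets went opposite ways. A split that leaves 2 control arrays on each side was not possible, and 1 of 1 against 2 was not made for this pair. Part of the excess may come from the shared controls. The simulated covariance was at most 0.0237, which argues against sharing as the whole cause.

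A direct comparison of LBD37 with LBD38 overexpressers gave 11 probe sets, 2 higher and 9 lower with LBD37, and 3151 at an unadjusted p under 0.05 (limma). AT3G03920 was 3.32-fold higher with LBD37 (11.85 ± 0.07 against 10.12 ± 0.16, n = 3, adjusted p = 3.57e-09). AT1G59265, AT2G44970, AT2G33850, AT1G04780 and AT2G47010 were 3.21-, 3.18-, 2.48-, 2.1- and 1.61-fold lower, with adjusted p from 5.11e-09 to 0.0174. The unnamed probe sets 246996_at and 252220_at differed 66.5-fold (higher with LBD37) and 112-fold (lower). Against wild type each was raised in only 1 line, 246996_at 35.1-fold with LBD37 and 252220_at 52.6-fold with LBD38. In the other line each read lower than in wild type. The log2 signal of 246996_at averaged 7.081 with LBD38 against 8.002 in wild type. That of 252220_at averaged 6.175 with LBD37 against 7.268 in wild type. The annotation used does not tell whether these probe sets belong to the targeted genes. The lists gave an adjusted p = 0.0645 for anthocyanin synthesis (median −0.27) and 0.0587 for glucosinolate synthesis (median −0.26, 2 lower adjusted over the list alone), and the other fixed lists lay between 0.0892 and 0.973. Without the LBD37 overexpresser's replicate 3 these medians were −0.09 and −0.16, and the anthocyanin median was −0.43 without the LBD38 overexpresser's replicate 1.

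The 25S ribosomal RNA probe set read 1.12 higher with LBD37 than with LBD38 (exact permutation p = 0.1, the smallest possible). The count rose to 741 without the LBD37 overexpresser's replicate 2, and it was 20 without the LBD38 overexpresser's replicate 1. The call of AT2G33850 was lost without the LBD37 overexpresser's replicate 1 and without the LBD38 overexpresser's replicate 2 or 3, and AT2G47010 also lost its call without single arrays, with an adjusted p = 0.0858 without replicate 3 of the LBD37 overexpresser.

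To relate the overexpressers to the nitrogen response, the direction of each called probe set was compared. Of the 4203 probe sets changed with LBD37, 2967 (70.6%) had moved the other way under nitrogen depletion in wild type and 313 (7.45%) the same way. The transporter NRT2.5, the starch gene APL3, the anthocyanin gene DFR and AT1G64360 were among the 1885 that nitrogen depletion raised and LBD37 lowered, where independent lists would share 603.6, and AT2G19970 and SPCH among the 1082 of the reverse kind (436.5). With LBD38, 3074 of 4076 (75.4%) moved the other way, 1609 (463.6) and 1465 (561.1), and 283 (6.94%) the same way. STZ was among those raised by nitrogen depletion and raised again in both overexpressers.

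Both comparisons use the nitrogen-depleted wild-type arrays with opposite sign. The observed correlations were −0.535 (LBD37) and −0.608 (LBD38). Unchanged groups simulated with such sharing gave means of −0.445 (−0.832 to 0.580) and −0.475 (−0.857 to 0.529). The simulated groups hold no real change, so their correlations do not measure what sharing adds to the observed ones. The covariances are the values to compare. The covariances were −0.112 and −0.124 against simulated means of −0.00682 and −0.0073, differences of −0.105 and −0.116. With 1 of the 3 wild-type arrays used for nitrogen depletion and the other 2 for the overexpresser, no wild-type array was shared. The covariance then stayed between −0.103 and −0.112 for LBD37 and between −0.113 and −0.121 for LBD38. The correlations lay between −0.471 and −0.533 for LBD37 and between −0.527 and −0.588 for LBD38. This split was chosen after the overlap was seen. The count of opposite calls for LBD37 was 1937 without wild-type replicate 1, and at most 3029 without another array.

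**Figure D4:**
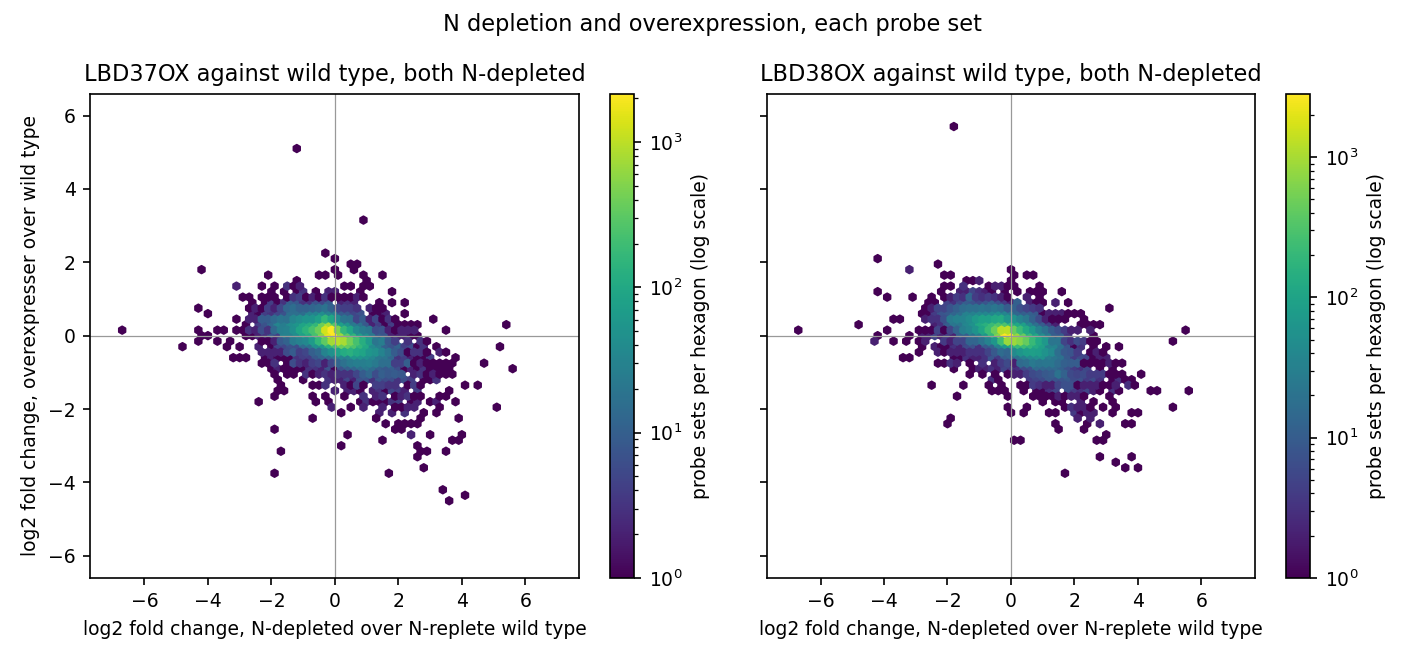
Density of the 22746 probe sets by log2 fold change under nitrogen depletion in wild type (horizontal) and in the LBD37 (left) or LBD38 (right) overexpresser against wild type (vertical). The cloud slopes downward, with r of −0.535 and −0.608.

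The lbd37 mutant was compared with wild type under full nitrogen supply, the question being which transcripts depend on LBD37 there. AT3G10040, a trihelix factor of the hypoxia response, was 2.01-fold higher (6.65 ± 0.34 against 5.64 ± 0.17, n = 3, limma adjusted p = 0.00288), and AT4G19430 2.00-fold (adjusted p = 0.00725). AT3G10930, AT4G10270, STZ, AT4G23680, AT4G27280 and AT3G48650 were 2.93-, 2.66-, 2.63-, 2.45-, 2.31- and 2.02-fold higher, with adjusted p from 0.00725 to 0.0441. AT3G12900, a hydroxylase of coumarin synthesis, was 1.97-fold lower (adjusted p = 0.00854) and AT1G74770, an E3 ubiquitin ligase, 1.51-fold (adjusted p = 0.0405). AT4G36700, AT1G51830, AT3G07720 and AT3G56260 were 1.94-, 1.58-, 1.47- and 1.43-fold lower.

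The anthocyanin genes were at a median of 0.30 in lbd37 (camera, adjusted p = 0.0954), DFR at 10.27 ± 0.41 against 9.97 ± 0.38. That median was 0.13 without wild-type replicate 3 and 0.45 without wild-type replicate 1. The early flavonoid list passed in the downward direction (median −0.28, camera adjusted p = 0.0267, or 0.535 with an estimated correlation). In it, CHS and CHI had no matched probe set. CHIL was at −0.28, UGT78D1 at −0.42 and UGT78D3 at −0.07, of which 2 passed only when adjusted over the list alone. The senescence and autophagy list passed upward (median 0.04, adjusted p = 0.0394; adjusted p = 0.535 with an estimated correlation) although its members did not pass singly, WRKY53 being at 0.71 and WRKY6 (AT1G62300) at 0.24. Its median was 0.02 without wild-type replicate 1 and 0.08 without wild-type replicate 3. The other fixed lists had adjusted p from 0.368 to 0.921. NRT2.5 and APL3 were at 0.17 and 0.42, neither past the threshold.

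The comparison gave 43 probe sets, 31 higher and 12 lower (limma), 1688 at an unadjusted p under 0.05, and 8 that rose at least 2-fold. The arrays did not overlap at 13.95% of probe sets, against 10% by chance. Of the 14 named genes, AT3G10040 and AT4G19430 stayed past the threshold when any 1 array of the comparison was left out, and STZ, AT3G48650 and AT1G74770 lost their call in each such fit. The other 9 lost it in some, AT3G12900 only without the mutant's replicate 3 (adjusted p = 0.0563). The count was 11, 18 and 15 without the mutant's replicates 1, 2 and 3, 17 and 21 without wild-type replicates 1 and 2, and 77 without the LBD37 overexpresser's array that stood apart, which enters only through the shared estimate of spread.

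The lbd38 mutant differed from wild type at more probe sets. QQS (AT3G30720), a gene of no known homology that affects the allocation of carbon and nitrogen to starch and protein, was 3.92-fold higher (7.80 ± 0.07 against 5.84 ± 0.14, n = 3, limma adjusted p = 2.15e-08), and AT5G54530 2.85-fold (8.23 ± 0.13 against 6.72 ± 0.20, adjusted p = 1.24e-06). PDF1.2 was 6.04-fold higher with a wide spread (7.01 ± 0.99 against 4.41 ± 0.17, adjusted p = 0.00356). Its wild-type signal lay below the lower quartile of every array, so this fold is rough. The thionin gene AT1G66100, PDF1.2b, AT4G01390, AT1G68600 and AT1G66090 were 4.00-, 3.76-, 3.57-, 3.24- and 2.53-fold higher. AT2G17740, AT4G36700, the glutaredoxin AT4G15680 and the peroxidase AT5G64120 were 2.52-, 2.18-, 2.17- and 2.07-fold lower, and AT4G12490, AT5G16980, CYP71B26 (AT3G26290) and AT5G58570 1.93-, 1.88-, 1.85- and 1.85-fold.

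Of the fixed lists the jasmonate list passed in lbd38 (median 0.30, adjusted p = 0.00403; adjusted p = 0.0646 with an estimated correlation), with 1 of 3 genes past the threshold, PDF1.2, or 2 adjusted over the list alone; JMT was at 0.30. The anthocyanin genes were at a median of −0.03 (adjusted p = 0.911; −0.16 without wild-type replicate 3 and 0.13 without the mutant's replicate 1), and the remaining lists had adjusted p from 0.115 to 0.945. AT3G25790, a nitrate-responsive transcription factor gene, rose 1.61-fold (adjusted p = 0.00744) and AT5G41670, for a phosphogluconate dehydrogenase, 1.38-fold (adjusted p = 0.0292).

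The comparison gave 270 probe sets, 134 higher and 136 lower (limma), 40 and 12 of them at least 2-fold, and no overlap between arrays at 18.5% of probe sets against 10% by chance. After each array was centred on its median the split was 196 higher and 125 lower. The 25S ribosomal RNA probe set read 8.09 against 8.64 in wild type (exact permutation p = 0.1, the smallest possible). The count was 134 and 171 without wild-type replicates 1 and 2, 122 and 120 without the mutant's replicates 1 and 3, and 491 without the LBD37 overexpresser's replicate 3. PDF1.2b, AT2G17740, AT4G12490, AT4G15680 and CYP71B26 lost their call without some array, and the other 11 named genes kept theirs.

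The mutants shared 7 probe sets higher and 4 lower than wild type, where independent lists would share 0.183 and 0.0717. STZ, AT4G27280, AT3G48650 and AT5G52750 were higher in both, and AT3G12900 and AT4G36700 lower in both. AT2G36690 went opposite ways, at 0.76 in lbd37 and −0.79 in lbd38. AT5G52750 and AT2G36690 were chosen after their values were seen. Across probe sets the fold changes correlated at r = 0.307. Unchanged groups simulated with a shared control group gave a mean of 0.460, without the spread that real changes add. The covariance was 0.00767 against a simulated mean of 0.00725. Without replicate 3 of the replete wild type r was 0.477, and part of the overlap may come from the shared controls.

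A direct comparison of lbd37 with lbd38 gave 591 probe sets, 341 higher and 250 lower in lbd37 (limma), with 37 and 34 changed at least 2-fold and no overlap between arrays at 24.3% of probe sets against 10% by chance. AT4G22470 was 4.15-fold higher in lbd37 (9.38 ± 0.33 against 7.33 ± 0.18, n = 3, adjusted p = 0.00545). AT2G17740, AT2G36690, AT4G23680 and AT1G23390 were 3.09-, 2.94-, 2.54- and 2.42-fold higher. PDF1.2 was 6.23-fold lower (adjusted p = 0.0016) and QQS 3.25-fold (6.11 ± 0.10 against 7.80 ± 0.07, adjusted p = 2.55e-07). AT1G66100, AT5G54530 and TBL26 (AT4G01080) were 3.42-, 3.12- and 2.85-fold lower. Each of these 10 genes kept its call when any 1 array was left out.

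Among the lists, jasmonate genes were lower in lbd37 than in lbd38 (median −0.33, adjusted p = 0.00262; adjusted p = 0.0882 with an estimated correlation), with PDF1.2 past the threshold and 2 genes adjusted over the list alone. Root markers (median −0.31, adjusted p = 0.0119; adjusted p = 0.353 with an estimated correlation) and early flavonoid genes (median −0.25, adjusted p = 0.0248; adjusted p = 0.353 with an estimated correlation) passed as lists with 2 genes each lower when adjusted over the list alone. AT4G26010, among the root markers, was at −0.66. AT3G25790 and ATG8B differed by −0.92 and 0.44, both past the threshold. The count of probe sets lay at 292, 306 and 350 without lbd37 replicates 1, 2 and 3, at 327, 388 and 296 without those of lbd38, and at 924 without the LBD37 overexpresser's replicate 3. It was higher still with array weights and when only the groups compared were fitted, as given below. Leaf markers, which did not pass as a list, had a median of 0.24 (adjusted p = 0.173), and 0.14 without the replicate 1 of lbd38.

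Set against the nitrogen response, 26 of the 43 lbd37 probe sets moved the same way as under nitrogen depletion and 9 the other way. The same-way calls were 19 higher and 7 lower, where independent lists would share 7.3 and 3.2. Of the 270 lbd38 probe sets 158 moved the same way (88 higher and 70 lower, against 31.5 and 36.2) and 72 the other way. For the opposite calls independent lists would share 2.8 and 8.3 (lbd37, observed 4 and 5) and 32.02 and 35.7 (lbd38, observed 47 and 25). Nitrogen depletion and each mutant comparison subtract the same replete wild-type arrays, which alone pushes calls the same way. Independent lists do not allow for this, and no split of these arrays was made for the mutants. AT3G25790 and STZ rose under nitrogen depletion and in lbd38. The covariance with lbd38 was 0.0359 against a simulated 0.00706 (at most 0.0223), and with lbd37 0.0126 against 0.00686 (at most 0.0210), within the range that unchanged groups gave. The correlations were 0.325 and 0.140. The simulated means of 0.475 and 0.469 come from groups without real change and are not comparable with them. The counts of opposite calls for lbd37 were 4 and 2 without replete wild-type replicates 1 and 2 and 3 without any 1 of the mutant arrays. For lbd38 they were 36 and 46 without the same wild-type replicates and 45 and 37 without the mutant replicates 1 and 3. For LBD38, 90 probe sets changed in opposite directions in overexpresser and mutant (42 and 48, against 12.6 and 11.6 for independent lists) and 26 in the same direction, among them PDF1.2 and STZ. For LBD37 the counts were 15 (4 and 11, against 0.865 and 3.49) and 9 (8 and 1, against 2.23 and 1.35). The covariance was −0.0131 for LBD38, outside the simulated range (at least −0.0088), and −0.00603 for LBD37, within it (at least −0.0070). The correlations of −0.128 (LBD37) and −0.233 (LBD38) were −0.043 without replete wild-type replicate 1, −0.084 without lbd37 replicate 1, and −0.146 without lbd38 replicate 1. Overexpressers and mutants were grown under different nitrogen supply, so that genotype and supply differ together between them.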

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

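The set of mitochondrial genes used in this part was chosen after the results it bears on were seen. The same holds for the splitting of the wild-type arrays into 1 and 2 given in the Results.

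The direct tests between lines drew attention to differences between groups under the same contrast. LBD37 and LBD38 overexpressers differed at 11 probe sets, with log2 differences of 1.73 for AT3G03920, −1.68 for AT1G59265, −1.67 for AT2G44970, −1.31 for AT2G33850, −1.07 for AT1G04780 and −0.69 for AT2G47010. The lbd37 and lbd38 mutants differed at 591 probe sets, with 2.05 for AT4G22470, 1.63 for AT2G17740, 1.56 for AT2G36690, 1.34 for AT4G23680 and 1.27 for AT1G23390. On the other side were −2.64 for PDF1.2, −1.78 for AT1G66100, −1.70 for QQS, −1.64 for AT5G54530 and −1.51 for TBL26. The control probe set for 25S ribosomal RNA, which the limma tests left out, was 1.69 higher in the LBD37 overexpresser than in wild type.

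The first pattern weighed is that 70.6% of the probe sets changed by LBD37 and 75.4% of those changed by LBD38 had moved the other way under nitrogen depletion. Sharing of the wild-type arrays was tested by the covariance of fold changes, which was −0.112 and −0.124, whereas the most negative of 100 simulated values was −0.0191 and −0.0225. A trend of fold change with signal level was tested by taking out a smooth trend on mean signal, which left −0.109 and −0.124. These values argue against either as the whole cause. A biological explanation may be that the overexpressed factors hold back part of the response to nitrogen depletion, and it stays a hypothesis found and tested on the same data, in which slower growth or nitrogen use of the lines was not tested.

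The second pattern is that 57 of 63 genes encoded in the plastid fell under nitrogen depletion (median −0.927), while 24 of 63 rose in the LBD37 (median 0.403) and 45 of 63 in the LBD38 overexpresser (0.555). The plastid list calls in these comparisons were lost with an estimated correlation (adjusted p of 0.216 and 0.213, 0.191 for both lists, and 0.129 for both). Uneven priming of RNA without poly(A) tails would move mitochondrial transcripts alike, and the 16 mitochondrial genes had medians of −0.029, 0.037 and 0.060. Their mean signal per array was low, 5.45 to 5.67 against 8.54 to 9.91 for the plastid genes. The lower quartiles of the arrays were 5.19 to 5.34. Signal so low can hide a shift, so these medians do not decide on uneven priming. The array that stands apart was excluded as the cause of the LBD37 value, since the median without it was 0.476. The 25S ribosomal RNA signal was higher in the overexpressers (1.69 and 0.57) and also under nitrogen depletion (0.55), where plastid transcripts fell. Leaf markers moved with the plastid genes (medians −0.81, 0.26 and 0.32) and root markers against them (0.63, −0.37 and −0.21), although PYK10 among the root markers (−1.27) and FMA among the leaf markers (0.24) went the other way under nitrogen depletion. A different share of leaf and root tissue therefore stays open, with 7 markers measured.

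The third pattern is the higher level of rapid defence and calcium signalling genes in lbd37. Their mean was 0.443 above wild type and their median change was 0.29, with only STZ past the threshold. In lbd38 the list mean was 7.01, against 7.24 in lbd37 and 6.80 in replete wild type. Within groups the list mean ranged over up to 0.389 between replicate arrays (LBD37 overexpresser), 0.242 in lbd37 and 0.054 in replete wild type. A range between single arrays is not on the same footing as a difference of group means. The list means of the lbd37 arrays (lowest 7.16) did not overlap those of replete wild type (highest 6.82). The mutation and handling that differs between groups still cannot be told apart, because the labels give no order or day of harvest.

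The 6 arrays of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. Each other split mixes both groups on each side, so a real difference adds to its spread and lowers its count. Low counts there do not measure what chance alone would give. For nitrogen depletion 1 split of 10, the real one, gave 11412 probe sets and the highest other 0. For LBD37 and LBD38 overexpression the real splits gave 4203 and 4076 and the highest other 1 each. For lbd37, lbd38 and lbd37 against lbd38 the real splits gave 43, 270 and 591 and the highest others 2, 1 and 0. For LBD37 against LBD38 overexpression 2 splits gave at least the real 11, the other giving 132. That split sets the LBD37 overexpresser's replicates 1 and 3 with the LBD38 overexpresser's replicate 2 against the other 3 arrays. Whether it reflects chance or a structure of the samples that crosses genotype was not tested.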

How the results depend on the processing

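Choices and alternatives were set before the data were examined, with some exceptions. Leaving out replicate 3 of the LBD37 overexpresser in comparisons that do not contain it was chosen after seeing the data. So were the set of mitochondrial genes and the splitting of the wild-type arrays into 1 and 2. No named gene and no list call past the threshold changed direction, while the larger side of some counts did: LBD37 had 2241 higher and 2195 lower after centring, LBD38 2114 and 2179 after centring, and nitrogen depletion 4585 and 4386 without dim probe sets. Of the totals and gene values under alternatives 1496 stayed, 232 were weaker and 10 stronger. Staying meant keeping the side of the threshold or lying within 1.5 times the count, or, for correlations, within 1 jackknife standard error. This bound for correlations was computed from the same fits that leave out 1 array. Such a fit can hardly exceed it, so its label shows no stability. Among correlations within that bound that moved by over 1.5 times, overexpresser against mutant went from −0.128 to −0.043 and −0.084 (LBD37) and from −0.233 to −0.146 (LBD38), and the mutants' shared response from 0.307 to 0.477, without 1 array. With only probe sets of 1 gene, fewer being tested, the counts were 6212, 2182, 2040, 7, 25, 111 and 272 for nitrogen depletion, LBD37, LBD38, LBD37 against LBD38 overexpression, lbd37, lbd38 and lbd37 against lbd38. With a 2-fold minimum they were 2290, 385 and 430 for the first 3 and 8, 52 and 71 for lbd37, lbd38 and the mutants against each other. An adjusted p under 0.01 left 2137 (LBD37), 2462 (LBD38), 13 (lbd37), 97 (lbd38) and 241 (lbd37 against lbd38). Array weights gave 33 between overexpressers, 76 for lbd37 and 1882 between mutants, and fitting only the groups compared gave 2067 for LBD37, 7 between overexpressers, 68 for lbd37 and 1239 between mutants; the cause was not tested. With an estimated correlation 3 of 60 list calls remained. Leaving out 1 array gave 2736 to 4822 for LBD37, 2603 to 4927 for LBD38, 8 to 741 between overexpressers, 11 to 77 for lbd37, 120 to 491 for lbd38 and 292 to 924 between mutants. Probe sets called opposite to nitrogen depletion then numbered 1937 to 3029 for LBD37, 2 to 13 for lbd37 and 36 to 67 for lbd38.

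The replicate block gave 11589, 4421, 4228, 13, 41, 306 and 638 probe sets in the order above, and 93 of 94 named genes and 56 of 60 list calls kept their call. The replicate numbers did not meet the rule for pairing, which asks every pair for a correlation over 0.1: over 45 pairs with the same number the deviations correlated at a mean of 0.0447 (−0.251 to 0.260, 15 over 0.1), against −0.0221 for different numbers. Of 18 arrays 10 correlated best with their own number, where chance gives about 6. Replicate 2 had the highest median in every group (7.04, 7.03, 7.06, 7.03, 7.00 and 6.99). It also had the highest ratio of 3' to 5' actin signal in every group but lbd38. The rule for pairing is so strict that failing it does not show the replicates to be unpaired, and a batch shared by number stays open. Of the 94 named genes 92 kept their call after quantile normalization again, 93 after centring, 89 with a trend, 92 with array weights and 87 with only the groups compared. The filter on dim probe sets kept 71 and left 23 untested, so low signal limits what can be said of these. Of the 60 list calls fry kept 38, lost 22 and gained 11, and using all probe sets of a gene kept 60. Under the filter on dim probe sets 50 could be tested, of which 38 were kept and 12 lost, and 4 were gained. The targeted genes had no probe set by name and could not be followed under any alternative.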

Other observations

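The 17 added lists were chosen after the probe annotation was read and before any comparison was run, and the genes named from them were chosen after their values were seen.

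In brackets below stand the list median, the camera adjusted p and, last, the adjusted p with an estimated correlation. Under nitrogen depletion 39 of 43 measured plastid-encoded photosynthesis genes fell (median −0.78, camera adjusted p = 8.6e-09; adjusted p = 0.216 with an estimated correlation), as did 18 of 20 plastid genes of gene expression (−1.31, 4.24e-08; 0.213) and 19 of 22 nuclear genes for photosynthesis and chlorophyll (1 rose, −0.92, 2.85e-07; 0.355). All 13 autophagy genes rose (0.99, 1.22e-10; 0.02), and so did 9 of 15 genes of rapid defence and calcium signalling (0.71, 4.96e-05; 0.17), with CML41 10.8-fold higher. Ureide, asparagine and ornithine genes (5 of 8 rose, 0.61, 0.000515; 0.17), flavonoid and anthocyanin genes (6 of 8 rose, 1.19, 0.000515; 0.366) and protein folding genes (9 of 14 rose and 2 fell, 0.45, 0.00748; 0.338) passed upward, and mitosis and histone genes downward (15 of 17 fell, −0.75, 5.06e-05; 0.355). The sugar transporter SWEET13 rose 9.83-fold within a list that went both ways (4 of 14 rose and 7 fell, adjusted p = 0.949). Lists for branched-chain amino acids, tau-class glutathione transferases, expansins, cold and dehydration, auxin, iron and stomata had adjusted p of 0.74, 0.156, 0.84, 0.395, 0.945, 0.298 and 0.233.

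With LBD37 overexpression, plastid photosynthesis genes (14 of 43 rose, median 0.35, camera adjusted p = 5.7e-08; adjusted p = 0.191 with an estimated correlation) and plastid gene expression genes (10 of 20 rose, 0.43, 3.05e-07; 0.191) passed upward, while the nuclear photosynthesis list had an adjusted p = 0.418. Autophagy genes (7 fell, −0.36, 5.72e-06; 0.17), tau-class glutathione transferases (5 fell and 1 rose, −0.37, 0.00491; 0.192), folding genes (7 fell, −0.26, 0.00444; 0.192) and flavonoid and anthocyanin genes (5 fell and 2 rose, −0.74, 0.0202; 0.583) passed downward, and stomatal genes upward (2 rose, 0.22, 0.016; 0.191). With LBD38, 30 of 43 and 15 of 20 plastid genes rose (0.54, 6.56e-17; 0.129, and 0.66, 9.15e-12; 0.129), as did 9 of 22 nuclear photosynthesis genes (1 fell, 0.34, 3.9e-05; 0.413), 4 mitosis and histone genes (0.27, 0.00113; 0.413) and 1 stomatal gene (0.40, 0.00573; 0.175). Autophagy (4 fell, −0.22, 0.00113; 0.175) and folding genes (6 fell, −0.23, 0.00298; 0.192) passed downward. The median of stomatal genes with LBD37 was 0.41 without that line's replicate 3. With LBD38 the median of autophagy genes was −0.14 without wild-type replicate 1 and that of mitosis and histone genes 0.17 without that line's replicate 2. SWEET13 changed by −2.11 with LBD37 and by −1.78 with LBD38.

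In lbd37 the rapid defence and calcium list passed with 1 gene past the threshold, STZ, or 7 adjusted over the list alone (median 0.29, camera adjusted p = 4.11e-12; adjusted p = 0.0264 with an estimated correlation). The plastid lists passed at medians of 0.17 (3.68e-08, then 0.535) and 0.19 (3.3e-05, then 0.535), although no single plastid gene passed in limma. In lbd38 the rapid list passed with 1 gene higher (0.15, 0.0143; 0.816), but its median was 0.02 without the mutant's replicate 3 and 0.25 without wild-type replicate 2. Between mutants the plastid lists were higher in lbd37 (0.21, 1.53e-06; 0.353, and 0.32, 3.92e-07; 0.353), where root markers had a median of −0.31 and leaf markers of 0.24, and between overexpressers the nuclear photosynthesis list was lower with LBD37 (−0.21, 4.67e-06; 0.503), as was plastid photosynthesis (−0.18, 0.000582; 0.503), although no single member of either passed in limma at an adjusted p of 0.05. These medians were −0.08 and −0.07 without the LBD37 overexpresser's replicate 3 and −0.36 and −0.25 without its replicate 2. Further lists passed with an adjusted p near the threshold and not with an estimated correlation: flavonoid and anthocyanin (0.0358), autophagy (0.049) and tau-class glutathione transferase genes (0.049) between overexpressers (each 0.503), and nuclear photosynthesis (0.0488, then 0.805) and tau-class glutathione transferase genes (0.0488, then 0.552) in lbd37. Between mutants these were rapid defence and calcium (0.0142, then 0.353), ureide, asparagine and ornithine (0.0196, then 0.353), branched-chain amino acid (0.0243, then 0.401), tau-class glutathione transferase (0.027, then 0.386), expansin (0.027, then 0.401) and SWEET genes (0.0395, then 0.353).

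The medians of lists moved by over 1.5 times when 1 array was left out in 15 of the 60 list tests past the threshold, each keeping its sign, and in 113 of the 129 others, of which 56 changed sign. Medians of lists that did not pass are therefore given only as measured values.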
